A study of Rattus norvegicus with 36 samples.

How the data were processed

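Total RNA of retina from male Long Evans hooded rats was measured on Agilent 4x44K rat arrays in 1 colour. Per the labels, pressure in the anterior chamber was raised to 110 mmHg for 60 min through a cannula, sham eyes were cannulated without it, and 200 ng of RNA was labelled with Cy3. The groups were 2 treatments (IR and sham) by 3 times (0 h, 24 h and 7 d), with 6 arrays each. The arrays lay on 9 slides with 1 scan date. No slide held IR and sham of the same time, so slide and treatment cannot be told apart within a time.

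The deposited scanner files, made by the authors with Agilent Feature Extraction 9.5.3.1, hold an intensity per spot, as the processed signal and as mean signal and background median, and flags of 0 or 1 (a unit of other kind, per the file headers) such as well above background. The deposited value table is in log2 with each probe centred near its median over the 36 columns (largest absolute probe median 0.0149). How the authors scaled the arrays to each other in it is not stated, and its column medians ran from -0.11 to 0.12 on this unknown scale. It covers 23890 probes, of which 23867 matched the scanner files. Each column was compared with every array on the matched probes after centring, with a tolerance of 0.01 on the log2 scale: 28 columns followed their own array and 8 followed another array of the same group.

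Control spots and spots marked non-uniform or as population outliers were left out, repeated spots of a probe were averaged on the log2 scale, and saturated spots were kept. Values were log2 processed signal minus the 75th percentile of the array. Of 41012 probes, 32208 were well above background on at least 4 of 6 arrays of at least 1 group. Each gene was represented by its brightest probe, which gave 27410 genes or identifiers. Probes were named from the reference by their accession (10735 probes), symbol (5571), synonym (3729), gene number (1217) or another accession (42), and the remaining 19718 kept the name in the file. Positions are those of the probe annotation on rn3. The share of spots well above background was 66.0% to 73.9% in IR 0 h, 74.9% to 79.8% in IR 24 h, 68.8% to 77.5% in IR 7 d, 67.4% to 71.5% in sham 0 h, 70.7% to 72.5% in sham 24 h and 23.5% to 72.0% in sham 7 d.

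Arrays of a group were compared with each other against the noise of repeated spots. Arrays that differed by less than the sampling noise were IR 0 h replicates 1 and 5, IR 24 h replicates 5 and 6, sham 0 h replicates 4 and 5, sham 24 h replicates 1 and 2, and sham 24 h replicates 3, 4 and 5. Each such set was counted as 1 sample in mean ± SD. The replicate numbers were not used as pairs. Of 18 pairs of IR and sham with the same number, 7 had a correlation of residuals over 0.1 and 4 were the best match of their arrays.

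Genes were tested with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) on the 6 group means of all 36 arrays. There were 9 contrasts: IR against sham at each time, the differences of these between times, and sham between times. Tests were two-sided, with Benjamini-Hochberg adjustment within the contrast and an adjusted p under 0.05 for a call. A fold change is given as at least N-fold where 1 of the 2 groups lay at background. No size is given where at most 1 array of both groups was well above background, or where a group of an interaction lay at background. 30 gene lists were tested with camera at its preset correlation of 0.01, adjusted over 90 tests for IR against sham and over 180 for the other contrasts, and again with an estimated correlation and with fry. Fry asks whether a list moves 1 way on balance and does not compare it with other genes. Members called within a list were also counted with p adjusted over the list alone.

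Groups, contrasts, tests, gene lists, the genes to name and the main alternatives were fixed before the data were examined. The genes named per IR against sham contrast were the 10 largest rises and falls among called genes with a symbol in the files and at least 5 of 6 IR arrays on the called side of the sham mean, up to 4 called members with the largest change per list (or the 1 with the smallest p where none was called), and 15 genes given whatever their result. For the other contrasts they were the 5 largest rises and falls. Some of the genes so chosen are not reported here. Genes named for the slides and for sham 0 h replicates 1 and 2 were chosen after their values were seen.

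The main choices were varied by normexp background correction (offset 50) of mean signal, quantile normalisation, median centring, no probe filter, a filter on 6 of 6 arrays and the mean of a gene's probes. Further choices varied were only the compared arrays, replicate number or slide as a block, array weights, the authors' table, adjusted p under 0.01, a 2-fold minimum, and each array left out in turn. For genes, an array was left out only in the contrasts that use its group. A block of scan date was not run, since there was 1 date. After the values were seen, the following were added: the arrays the authors' table holds, arrays closer than spot noise averaged, leaving out slide 9 or 5, further slide blocks, and other splits of the averaged samples. The fit was tested on simulated data with 50 genes changed at each size. With the spread of all arrays it called in the right direction 15 to 16 of 50 at 1 log2 unit, 37 to 39 at 2, 44 to 45 at 3 and 49 to 50 at 4; with the table arrays it called 34 to 40, 41 to 46, 48 to 50 and 50. False calls were 7 to 19 of 27181 unchanged genes. Errors that slides, unequal spread or arrays closer than sampling noise bring to the real arrays were not tested. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.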

Results

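Gene expression was measured in rat retina after ischemia and reperfusion (IR), an injury made by raising the pressure inside the eye to 110 mmHg for 60 min and then letting the blood flow return. Sham animals had the same surgery without the pressure rise. Retinas were taken at 0 h, 24 h and 7 d, which gave 6 groups of 6 arrays each, 36 arrays in all, on 9 slides. The labels describe the arrays of a group as biological replicates. Within groups, 7 pairs of arrays differed by less than the sampling noise of repeated spots and were counted as 1 sample in each mean ± SD, which left 30 samples. The share of spots well above background was 66.0% to 79.8% on slides 1 to 8 and 23.5% to 46.9% on slide 9, which held sham 7 d replicates 3 to 6. The number of arrays limits the precision of every value.

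The authors' table of values held only 30 of the 36 arrays, because 8 of its columns followed another array of their group. The 6 arrays it did not hold were sham 0 h replicates 1 and 2 and sham 7 d replicates 3 to 6. Sham 0 h replicates 1 and 2 stood apart from replicates 3 to 6, with higher Atf3, Hmox1 (log2 difference 5.17), Edn2 (7.00) and Lgals3 (5.62), genes that also rose in IR retina at 24 h, at 7 d or at both. C3, which rose in IR retina at 7 d, was not higher in them (difference -0.0021). For this reason each count is given for all 36 arrays, as planned, and for the 30 arrays that the authors' table holds, called the table arrays, a choice made after the values were seen. The p-values measure the spread between these arrays, and arrays closer than the sampling noise count as separate in them. With such arrays averaged, 99 calls of named genes ended and 243 values kept direction and call.

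**Figure D1:**
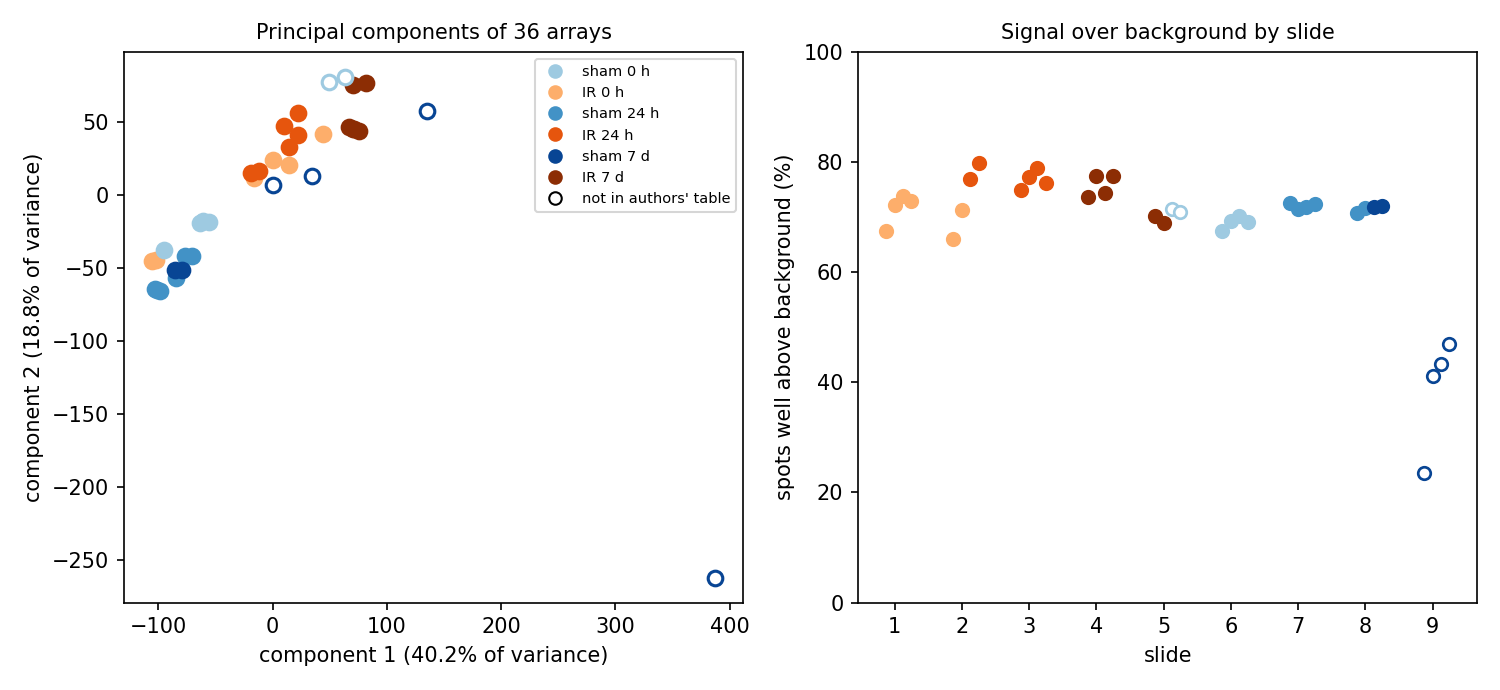
Left: the first 2 principal components (log2 scale) of the 36 arrays, 1 point per array coloured by group. Right: spots well above background (%) of each array by slide, with open points for the 6 arrays that the authors' table does not hold; the 4 arrays of slide 9 lie below all others.

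The comparison of IR with sham at 0 h asked what had changed at the end of ischemia. Genes of the pigment epithelium, the cell layer behind the retina, were higher in IR retina. They were listed beforehand as markers of another tissue. Whether a differing share of that tissue in the samples gave the rises was not tested. Rpe65, the isomerase that regenerates the visual chromophore, rose with a log2 fold change of 2.55 ± 0.48, adjusted p = 0.0146 (± SE, 6 against 6 arrays), from 0.053 ± 1.47 (SD, n = 5) in sham to 2.70 ± 0.34 (SD, n = 5) in IR on the log2 scale. With it rose Kcnj13, a potassium channel of that epithelium (2.09 ± 0.41, adjusted p = 0.0167), Slc16a8, its lactate transporter (1.98 ± 0.37, adjusted p = 0.0146), and Tyrp1, an enzyme of melanin synthesis (1.72 ± 0.33, adjusted p = 0.0166). Rpe65 is measured by a probe at chromosome 2, 257891567 to 257891626, on the rn3 build of the rat genome.

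In all, 35 of 27410 genes changed at 0 h, 30 higher and 5 lower. Every gene named as changed lay on the called side of the sham mean on 6 of 6 IR arrays. Of the 16 pigment epithelium and choroid markers measured, 4 rose, 0 fell and 12 were not called (13 and 0 adjusted over the list alone). Pigment epithelium and choroid markers had camera adjusted p = 8.41e-27, and 7.12e-04 with an estimated correlation. Other rises were in transferrin, Tf (1.76), and in the amino acid transporter Slc7a10 (1.63), the myosin Myo7a (1.56) and the organic anion transporter Slco1a5 (1.54). Pon1 (1.02), Nr0b2 (0.92) and the transcription factor Klf2 (0.82), an immediate early gene, rose less. The sign of Nr0b2 turned with another background correction. Gp2 fell at least 3.95-fold, and Trib3, a pseudokinase of the stress response (-1.59), and Cd276 (-1.14) fell.

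Lens genes were higher as a group at 0 h, though none of them was called genome-wide. Of the 13 crystallins, the proteins of the lens fibre, 0 rose, 0 fell and 13 were not called (13 and 0 adjusted over the list alone), with a median log2 fold change of 2.81. Crystallins had camera adjusted p = 2.64e-22, and adjusted p = 0.0824 with an estimated correlation. The crystallin mean ran from 0.62 to 5.33 over the IR 0 h samples. A differing share of lens tissue, weighed below for the fall at 24 h, may play a part here too. Of the 11 other lens fibre genes, 0 rose, 0 fell and 11 were not called (7 and 0 adjusted over the list alone; median 2.02). Lens fibre genes had camera adjusted p = 1.23e-11, and adjusted p = 0.129 with an estimated correlation. Crybb1 had 2.80 (adjusted p = 0.123) and Bfsp1, a lens filament protein, 2.53 (adjusted p = 0.102). Integrated stress and unfolded protein response genes were lower as a group (0 rose, 1 fell and 21 were not called; 0 and 3 adjusted over the list alone). Integrated stress genes had camera adjusted p = 6.37e-08, and 0.277 with an estimated correlation. The genes followed at every time that are given here were not called at 0 h: Atf3 -1.92 (adjusted p = 0.159), Fos 0.73 (adjusted p = 1.0), Gfap -0.83 (adjusted p = 1.0), Hmox1 -1.38 (adjusted p = 1.0), Il1b -1.46 (adjusted p = 1.0), Ccl2 -1.14 (adjusted p = 1.0), C3 -0.36 (adjusted p = 1.0) and Vegfa 0.31 (adjusted p = 1.0). The others were Hspb1 0.20 (adjusted p = 1.0), Aif1 -0.18 (adjusted p = 1.0), Pou4f1 0.49 (adjusted p = 1.0), Thy1 0.047 (adjusted p = 1.0), Glul 0.30 (adjusted p = 1.0) and Crybb2 3.33 (adjusted p = 0.703).

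Camera placed photoreceptor markers, amacrine and horizontal cell markers, Müller glia markers, hypoxia and glycolysis genes and synapse genes higher at 0 h. These had adjusted p from 4.34e-05 to 0.0145 (and adjusted p from 0.312 to 0.664 with an estimated correlation). It placed reactive gliosis genes, microglia and macrophage markers, chemokines and cytokines, complement genes, interferon and antigen presentation genes, heat shock genes, cell death genes, cell cycle genes and matrix remodelling genes lower. Those lists had adjusted p from 1.51e-16 to 0.0145 (and adjusted p from 0.266 to 0.663 with an estimated correlation). No member of these lists was called by limma. None of them was called with the table arrays, where sham 0 h replicates 1 and 2 are left out. Camera called there, and not over all arrays, neutrophil and lymphocyte markers as higher (1 rose, 0 fell; camera adjusted p = 0.00273, and adjusted p = 0.332 with an estimated correlation) and circadian genes as lower (1 rose, 1 fell; camera adjusted p = 0.00256, and adjusted p = 0.280 with an estimated correlation). There 1536 genes changed (981 higher, 555 lower), among them all 35 of the 35 above. In the table arrays 12 pigment epithelium and choroid markers rose and Atf3 fell with -0.88 (adjusted p = 0.00534). Hspb1 rose there (0.64, adjusted p = 0.00846). Glul (-0.48) and Thy1 (-0.23) were negative there and Gfap (0.31), Hmox1 (0.35), Ccl2 (0.091) and Aif1 (0.15) positive, with adjusted p from 0.442 to 0.930. Of the 35 calls, 4 stayed (0 falls) with arrays closer than the sampling noise averaged, so most named calls ended. The count was 1 with quantile normalisation, 3 with normexp, 6 with median centring and 6 with the slide as a random block. It was 13 without IR 0 h replicate 5, and no slide held both groups.

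The size differed by over 1.5 times with the table arrays for Rpe65 (1.66). With 1 array left out, calls ended for Rpe65, Tyrp1 and Pon1 (3 of 12 arrays each), Kcnj13 and Gp2 (4) and Nr0b2 (5). They also ended for Slc7a10 and Cd276 (6), Tf, Klf2 and Trib3 (11) and Slc16a8 (without sham 0 h replicates 1 and 2).

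The comparison at 24 h asked what had changed 24 h into reperfusion. Among the largest rises in IR retina was that of Atf3, a transcription factor induced by injury (4.44 ± 0.49, adjusted p = 4.60e-08; 0.059 ± 0.57 (SD, n = 3) in sham and 4.71 ± 0.16 (SD, n = 5) in IR). Others were Hmox1, the heme-degrading enzyme (4.44 ± 0.80, adjusted p = 1.30e-04), the AP-1 member Fosl1 (4.29 ± 0.97, adjusted p = 0.00151), and Clcf1, a cytokine of the interleukin 6 family (4.22 ± 0.63, adjusted p = 1.18e-05). Nes, the filament protein nestin (4.34 ± 0.70, adjusted p = 3.25e-05), and Cd36, a scavenger receptor (4.56 ± 0.75, adjusted p = 4.27e-05), rose as well. Crystallins fell against a split sham group (given below), with Cryaa at -4.88 ± 1.22, adjusted p = 0.00355 and Crybb2 at -4.83 ± 1.18, adjusted p = 0.00301. Of the neuronal genes, Pou4f1, a transcription factor of ganglion cells, fell by 2.02 ± 0.33 on the log2 scale (adjusted p = 4.07e-05), from -2.36 ± 0.21 (SD, n = 3) to -4.49 ± 0.31 (SD, n = 5).

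In all, 7294 of 27410 genes changed at 24 h, 4405 higher and 2889 lower. Of them, 4955 changed by at least 2-fold. Each gene named here as changed lay on the called side of the sham mean on 6 of 6 IR arrays. Further rises were in Cd8a (at least 6.14-fold higher), Ecel1 (4.36), Reg3b (at least 3.77-fold higher) and Bcl2a1 (4.14). Further falls were in Crybb3 (-4.46), Cryba2 (-4.45), Gja3 (-4.43), Omd (at least 9.66-fold lower), Cyp4f4 (-4.32), Cryba1 (-4.28) and Egfl6 (-3.99). The probe of Atf3 lies at chromosome 13, 107380795 to 107380853 and that of Hmox1 at chromosome 19, 13974162 to 13974221 (rn3).

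Cells of the immune system were marked by higher transcripts at 24 h. Of 29 microglia and macrophage markers, 11 rose, 0 fell and 18 were not called (14 and 1 adjusted over the list alone), among them Gpnmb (2.74), Cd14 (2.43) and Fcgr3a (2.43). Microglia and macrophage markers had camera adjusted p = 0.00244, and 0.592 with an estimated correlation. Of 17 neutrophil and lymphocyte markers, 9 rose, 0 fell and 8 were not called (14 and 0 adjusted over the list alone), among them Cd8a (at least 6.14-fold higher) and S100a8 (at least 1.83-fold higher). Neutrophil and lymphocyte markers had camera adjusted p = 6.66e-05, and 0.467 with an estimated correlation. Of 25 chemokines and cytokines, 10 rose, 1 fell and 14 were not called (10 and 1 adjusted over the list alone), with Ccl3 (3.86), Ccl7 (3.28), Ccl2 (2.01) and Il1b (1.86) among the rises. Chemokines and cytokines had camera adjusted p = 0.00601, and 0.467 with an estimated correlation. Of 30 interferon and antigen presentation genes, 16 rose, 0 fell and 14 were not called (20 and 0 adjusted over the list alone), among them Tap1 (3.46), Igtp (3.20) and Gbp2 (3.20). Interferon genes had camera adjusted p = 5.25e-06, and 0.467 with an estimated correlation. Complement genes went both ways: 2 rose, 2 fell and 15 were not called, with rises of C5ar1 (1.97) and Cfi (1.40) and falls of Cfb (-1.78) and C3 (-1.65). The microglial marker Aif1 had 0.27 (adjusted p = 0.618).

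Immediate early, integrated stress and cell death genes rose. Of 37 immediate early genes, 14 rose, 2 fell and 21 were not called (14 and 2 adjusted over the list alone), among them Junb (3.08) and Myc (3.02). Immediate early genes had camera adjusted p = 0.00129, and 0.428 with an estimated correlation. Fos itself had 0.33 (adjusted p = 0.647). Of 22 integrated stress and unfolded protein response genes, 12 rose, 0 fell and 10 were not called (12 and 0 adjusted over the list alone), among them the glutathione-degrading Chac1 (2.27) and the asparagine synthetase Asns (1.79). Integrated stress genes had camera adjusted p = 9.46e-06, and 0.312 with an estimated correlation. Of 29 cell death genes, 13 rose, 0 fell and 16 were not called (14 and 0 adjusted over the list alone), among them Bbc3, which triggers apoptosis (2.77), and the tumour necrosis factor receptor superfamily member Tnfrsf12a (2.76). Cell death genes had camera adjusted p = 6.89e-05, and adjusted p = 0.282 with an estimated correlation. Of 26 reactive gliosis genes, 11 rose, 4 fell and 11 were not called (11 and 4 adjusted over the list alone), among them Nes (4.34), Socs3 (3.22) and Edn2 (2.83). Reactive gliosis genes had camera adjusted p = 0.0145, and adjusted p = 0.664 with an estimated correlation. Gfap, the filament protein of reactive glia, had -0.10 (adjusted p = 0.918), and 0.16 (adjusted p = 0.930) with arrays closer than the sampling noise averaged. Sham itself was high in Gfap at 24 h, 4.75 above sham at 0 h with the table arrays. The Gfap level was -1.44 in IR at 24 h and -6.09 in sham 0 h replicates 3 to 6, of which 1 was well above background. The lack of a difference at 24 h thus does not mean a low level in IR. The heat shock gene Hspb1 had 0.17 (adjusted p = 0.691). Of 25 matrix remodelling genes, 10 rose, 3 fell and 12 were not called, and the metalloproteases Mmp12 (3.55) and Mmp3 (3.01) rose, though camera did not call the list (adjusted p = 0.0594).

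Genes of retinal neurons and Müller glia fell at 24 h. Of 28 photoreceptor markers, 0 rose, 10 fell and 18 were not called (0 and 10 adjusted over the list alone), with falls of cone arrestin Arr3 (-3.65), the short-wave cone opsin Opn1sw (-2.69) and rod transducin Gnat1 (-1.65). Photoreceptor markers had camera adjusted p = 4.52e-06, and 0.467 with an estimated correlation. Of 21 ganglion cell markers, 1 rose, 5 fell and 15 were not called (1 and 5 adjusted over the list alone), with falls of Pou4f1 (-2.02) and Nefl (-1.09) and a rise of Gap43, a growth cone protein (3.14). Ganglion cell markers had camera adjusted p = 0.0270, and 0.664 with an estimated correlation. Thy1 had -0.74 (adjusted p = 0.180). Of 16 bipolar cell markers, 0 rose, 5 fell and 11 were not called (0 and 5 adjusted over the list alone), with Prkca (-2.26) and Trpm1 (-1.28). Bipolar cell markers had camera adjusted p = 0.00143, and adjusted p = 0.467 with an estimated correlation. Of 23 amacrine and horizontal cell markers, 1 rose, 9 fell and 13 were not called (1 and 10 adjusted over the list alone), with falls of the acetylcholine vesicle transporter Slc18a3 (-3.21) and of Prox1 (-2.06). Amacrine and horizontal cell markers had camera adjusted p = 7.45e-06, and 0.282 with an estimated correlation. Of 29 synapse genes, 0 rose, 14 fell and 15 were not called (0 and 15 adjusted over the list alone), with the glutamate receptor subunits Grin2a (-3.32) and Gria4 (-2.47). Synapse genes had camera adjusted p = 7.81e-10, and adjusted p = 0.266 with an estimated correlation. Of 20 Müller glia markers, 3 rose, 9 fell and 8 were not called (3 and 10 adjusted over the list alone), with falls of Abca8a (-2.28) and Glul (-1.48), the latter being glutamine synthetase. Müller glia markers had camera adjusted p = 0.00235, and adjusted p = 0.467 with an estimated correlation.

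Lens genes and some metabolic genes fell at 24 h. Of 13 crystallins, 0 rose, 13 fell and 0 were not called (0 and 13 adjusted over the list alone; median -3.88). Crystallins had camera adjusted p = 2.28e-08, and adjusted p = 0.282 with an estimated correlation. Of 11 other lens fibre genes, 0 rose, 8 fell and 3 were not called (0 and 8 adjusted over the list alone; median -2.65), among them Lim2 (-3.42) and Bfsp2 (-3.10). Lens fibre genes had camera adjusted p = 2.90e-06, and adjusted p = 0.277 with an estimated correlation. Of 16 pigment epithelium and choroid markers, 1 rose, 4 fell and 11 were not called (1 and 6 adjusted over the list alone), with falls of Rrh (-3.27) and Kcnj13 (-1.83). Pigment epithelium and choroid markers had camera adjusted p = 0.00170, and 0.404 with an estimated correlation. Of 29 hypoxia and glycolysis genes, 0 rose, 6 fell and 23 were not called (0 and 6 adjusted over the list alone), among them hexokinase Hk2 (-1.72) and Vegfa, the vascular growth factor (-0.69). Hypoxia and glycolysis genes had camera adjusted p = 0.00545, and 0.664 with an estimated correlation. Of 19 cholesterol synthesis genes, 0 rose, 4 fell and 15 were not called (0 and 4 adjusted over the list alone), with Srebf2, which switches the pathway on, at -1.78. Cholesterol genes had camera adjusted p = 0.015, and 0.592 with an estimated correlation. Camera did not call oxidative stress genes (6 rose, 2 fell, 14 not called), heat shock genes (4 rose, 2 fell, 14 not called) and cell cycle genes (4 rose, 2 fell, 24 not called). Nor did it call anterior epithelium markers (4 rose, 1 fell, 8 not called), endothelium and pericyte markers (3 rose, 2 fell, 16 not called) and erythrocyte markers (0 rose, 1 fell, 7 not called). The same held for oxidative phosphorylation genes (0 rose, 0 fell, 22 not called), circadian genes (1 rose, 5 fell, 12 not called) and glucocorticoid targets (3 rose, 2 fell, 10 not called).

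With the table arrays, where each sham 24 h and IR 24 h array is kept, the fold changes at 24 h were identical and 17132 genes changed, because the spread within the other groups was smaller; they included 7294 of the 7294 above. With arrays closer than the sampling noise averaged, 2753 genes changed. With 1 array left out, calls ended for Il1b (4 of 12 arrays) and Edn2 (10 of 12).

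**Figure D2:**
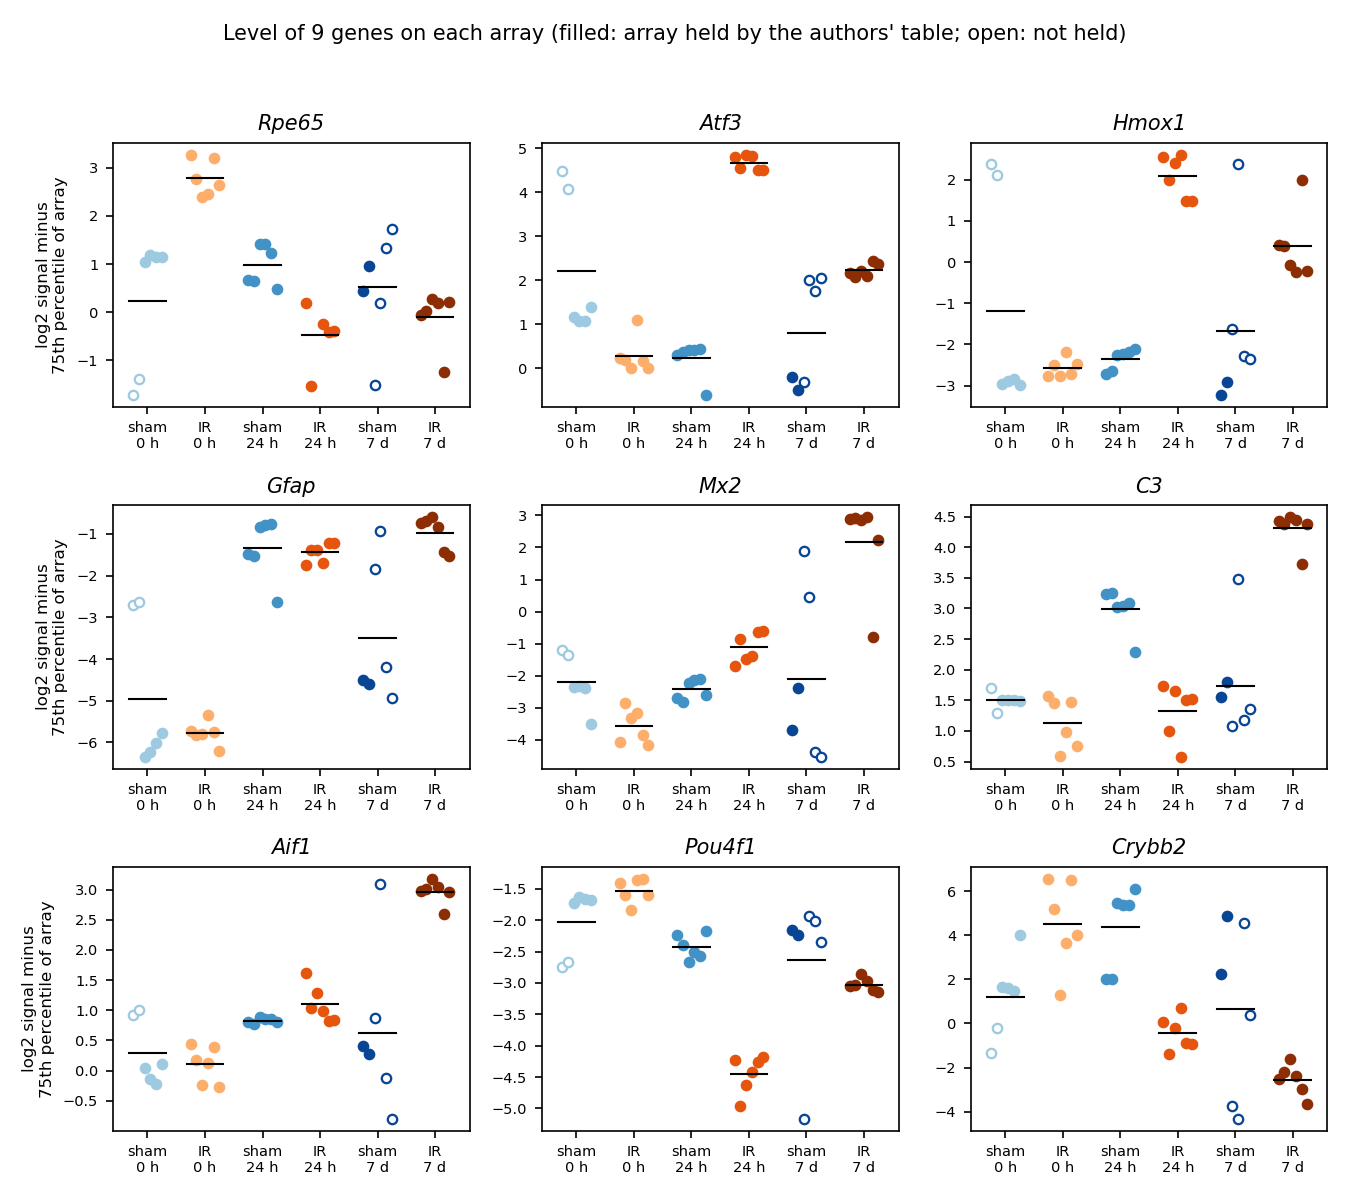
Log2 signal minus the 75th percentile of the array for 9 genes, 1 point per array in 6 groups, with a line at the group mean over 6 arrays; open points are the 6 arrays that the authors' table does not hold. Atf3 and Hmox1 were highest in IR at 24 h, C3 and Aif1 in IR at 7 d, and Pou4f1 was lowest in IR at 24 h by group mean.

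The comparison at 7 d asked what remained changed 7 d after injury. Interferon response genes were among the largest rises: Mx2, an antiviral GTPase (4.28 ± 0.74, adjusted p = 3.22e-04; -2.11 ± 2.69 (SD, n = 6) in sham and 2.18 ± 1.49 (SD, n = 6) in IR). Others were the guanylate-binding protein Gbp2 (4.05 ± 0.78, adjusted p = 8.81e-04), the transcription factor Irf7 (3.84 ± 0.45, adjusted p = 3.78e-06), and Oas1a (3.43), Rsad2 (3.42) and Oasl2 (3.40). Glial and complement genes rose as well, with Gfap at 2.54 ± 0.59, adjusted p = 0.00435 (-3.50 ± 1.68 (SD, n = 6) in sham and -0.97 ± 0.41 (SD, n = 6) in IR). Edn2, an endothelin, stood at 4.27 ± 1.05, adjusted p = 0.00654, the protease inhibitor Serpina3n at 3.86 ± 0.84, adjusted p = 0.00263 and C3, the central complement component, at 2.57 ± 0.28, adjusted p = 1.79e-06. The microglial marker Aif1 rose with 2.34 ± 0.35, adjusted p = 8.12e-05.

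In all, 3984 of 27410 genes changed at 7 d, 2979 higher and 1005 lower. Each named gene lay on the called side of the sham mean on 6 of 6 IR arrays. Of 30 interferon and antigen presentation genes, 26 rose, 0 fell and 4 were not called (29 and 0 adjusted over the list alone). Interferon genes had camera adjusted p = 3.93e-18, and 0.266 with an estimated correlation. Of 29 microglia and macrophage markers, 23 rose, 0 fell and 6 were not called (25 and 1 adjusted over the list alone), among them Lgals3 (3.33), Fcgr3a (3.14), Cd68 (3.00) and C1qc (2.59). Microglia and macrophage markers had camera adjusted p = 3.96e-15, and 0.266 with an estimated correlation. Of 19 complement genes, 10 rose, 0 fell and 9 were not called (13 and 0 adjusted over the list alone), among them C1s (3.52) and Cfb (2.80). Complement genes had camera adjusted p = 1.33e-09, and 0.266 with an estimated correlation. Of 26 reactive gliosis genes, 16 rose, 0 fell and 10 were not called (20 and 0 adjusted over the list alone). Reactive gliosis genes had camera adjusted p = 8.63e-10, and 0.282 with an estimated correlation. Of 29 cell death genes, 11 rose, 0 fell and 18 were not called (13 and 0 adjusted over the list alone), among them Fas (2.79), Casp12 (at least 3.24-fold higher) and Birc3 (2.23). Cell death genes had camera adjusted p = 3.53e-04, and adjusted p = 0.312 with an estimated correlation. Of 25 chemokines and cytokines, 7 rose, 0 fell and 18 were not called (11 and 0 adjusted over the list alone). Chemokines and cytokines had camera adjusted p = 0.0297, and 0.572 with an estimated correlation. Ccl2 had 1.24 (adjusted p = 0.212) and Il1b 0.39 (adjusted p = 0.736). Of 22 integrated stress and unfolded protein response genes, 4 rose, 0 fell and 18 were not called (4 and 0 adjusted over the list alone), with Atf3 at 1.42. Integrated stress genes had camera adjusted p = 0.00224, and 0.495 with an estimated correlation. The probe of Mx2 lies at chromosome 11, 37626509 to 37628404 and that of Irf7 at chromosome 1, 201607889 to 201607948 (rn3).

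Some neuronal, lens and sterol genes fell at 7 d. Of 21 ganglion cell markers, 0 rose, 4 fell and 17 were not called (0 and 4 adjusted over the list alone), with the neurofilaments Nefl (-1.03) and Nefm (-0.85). Ganglion cell markers had camera adjusted p = 1.35e-04, and 0.467 with an estimated correlation. Pou4f1 had -0.39 (adjusted p = 0.465) and Thy1 -0.086 (adjusted p = 0.913) over all arrays. Both fell with the table arrays, Pou4f1 with -0.83 (adjusted p = 2.30e-04) and Thy1 with -0.84 (adjusted p = 0.00331). Without sham 7 d replicate 3 they fell as well (-0.89 and -0.72). Of 23 amacrine and horizontal cell markers, 0 rose, 5 fell and 18 were not called (0 and 6 adjusted over the list alone), with the cholinergic genes Slc18a3 (-2.97), Slc5a7 (-2.57) and Chat (at least 2.96-fold lower). Amacrine and horizontal cell markers had camera adjusted p = 8.77e-04, and 0.467 with an estimated correlation. Of 13 crystallins, 0 rose, 5 fell and 8 were not called (0 and 7 adjusted over the list alone), with Crybb3 (-4.11), Cryba1 (-3.95) and Cryaa (-3.67). Crystallins had camera adjusted p = 5.73e-07, and adjusted p = 0.312 with an estimated correlation. Crybb2 had -3.23 (adjusted p = 0.0618). The lens fibre genes were lower as a group (0 rose, 0 fell and 11 were not called; 0 and 0 adjusted over the list alone). Lens fibre genes had camera adjusted p = 0.00304, and adjusted p = 0.467 with an estimated correlation. Of 19 cholesterol synthesis genes, 0 rose, 3 fell and 16 were not called (0 and 3 adjusted over the list alone), with Hmgcs1 (-1.23) among the falls. Cholesterol genes had camera adjusted p = 8.74e-06, and 0.312 with an estimated correlation. Camera also placed the synapse genes lower (0 rose, 3 fell and 26 were not called; 0 and 3 adjusted over the list alone). Synapse genes had camera adjusted p = 0.00601, and adjusted p = 0.572 with an estimated correlation. Other falls were in Dlk1 (-3.17), Cyb5r2 (-2.99), Mme (at least 2.22-fold lower), Dusp13b (-2.79) and Adrm1 (-2.74).

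Müller glia markers (4 rose, 0 fell and 16 were not called) included rises of apolipoprotein Apoe (2.51) and the transcription factor Sox9 (0.84). The adhesion receptor Icam1 (1.81) and osteopontin, Spp1 (2.12), rose. Of the photoreceptor markers, 2 rose, 0 fell and 26 were not called, with Sag, rod arrestin, at 1.89. Other lists not called at 7 d over all arrays were neutrophil and lymphocyte markers (4 rose, 0 fell, 13 not called), immediate early genes (4 rose, 1 fell, 32 not called), heat shock genes (2 rose, 0 fell, 18 not called) and bipolar cell markers (0 rose, 0 fell, 16 not called). Nor were pigment epithelium and choroid markers (2 rose, 0 fell, 14 not called), hypoxia and glycolysis genes (1 rose, 0 fell, 28 not called), matrix remodelling genes (5 rose, 1 fell, 19 not called) and cell cycle genes (5 rose, 1 fell, 24 not called) called. Blood and vessel markers had more rises than falls without a camera call: erythrocyte markers (4 rose, 0 fell, 4 not called) and endothelium and pericyte markers (4 rose, 0 fell, 17 not called). Fry, which does not compare a list with other genes, called both (adjusted p = 6.07e-05 and 0.0323). The remaining lists that camera did not call were oxidative stress genes (1 rose, 0 fell, 21 not called), anterior epithelium markers (1 rose, 0 fell, 12 not called), oxidative phosphorylation genes (0 rose, 0 fell, 22 not called), circadian genes (1 rose, 1 fell, 16 not called) and glucocorticoid targets (1 rose, 0 fell, 14 not called). Hmox1 had 2.05 (adjusted p = 0.0775), Fos -0.49 (adjusted p = 0.523), Vegfa 0.15 (adjusted p = 0.653) and Glul 0.14 (adjusted p = 0.864). Hspb1 rose (1.16).

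In the table arrays, which leave out the weak slide 9 and so hold only 2 sham arrays at 7 d, 11368 genes changed. Of the calls above, 2621 of 3984 were called in the same direction and 243 had the opposite sign. There 30 of 30 interferon genes rose, and 14 ganglion cell markers and 17 cholesterol genes fell. Hmox1 (3.44), Ccl2 (2.91) and Il1b (2.89) were called there. Camera also called lists there that it did not call over all arrays. It placed photoreceptor markers (2 rose, 6 fell; camera adjusted p = 6.95e-04, and adjusted p = 0.359 with an estimated correlation), hypoxia and glycolysis genes (2 rose, 8 fell; camera adjusted p = 0.00268, and adjusted p = 0.246 with an estimated correlation) and oxidative phosphorylation genes (0 rose, 2 fell; camera adjusted p = 0.0404, and adjusted p = 0.635 with an estimated correlation) lower. It placed neutrophil and lymphocyte markers (16 rose, 0 fell; camera adjusted p = 3.02e-06, and adjusted p = 0.120 with an estimated correlation), immediate early genes (22 rose, 4 fell; camera adjusted p = 7.80e-04, and adjusted p = 0.246 with an estimated correlation) and matrix remodelling genes (15 rose, 2 fell; camera adjusted p = 0.00965, and adjusted p = 0.433 with an estimated correlation) higher. Vegfa turned to -0.52. Without sham 7 d replicate 3, which had 23.5% of spots well above background, 8520 genes changed.

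The table arrays moved sizes by over 1.5 times, to Mx2 5.22, Irf7 4.52, Oas1a 5.33, Rsad2 5.48, Oasl2 4.54, Gfap 3.59, Edn2 5.57, Serpina3n 3.13, Fcgr3a 3.81, C1qc 3.64, Atf3 2.57, Crybb3 -5.30, Cryba1 -5.73, Cryaa -6.14, Dlk1 -4.78, Cyb5r2 -1.12, Dusp13b -1.33, Adrm1 -1.28 (call ended), Apoe 1.18, Icam1 2.60, Sag 0.034 (call ended) and Hspb1 2.05. The call of Mme ended with them. Leaving out IR 7 d replicate 5 and sham 7 d replicates 2, 3, 4, 5 and 6, each alone, moved sizes by over 1.5 times, with ranges of 3.80 to 5.08 for Mx2, 3.66 to 4.77 for Gbp2, 3.04 to 4.13 for Oas1a, 2.97 to 4.18 for Rsad2, 3.14 to 4.22 for Oasl2, 3.80 to 5.27 for Edn2, 3.27 to 4.51 for Serpina3n, 2.69 to 4.08 for Lgals3, 2.90 to 3.75 for Fcgr3a, 2.73 to 3.70 for Cd68, 3.16 to 4.15 for C1s, -4.93 to -3.49 for Crybb3, -5.06 to -3.31 for Cryba1, -4.84 to -2.75 for Cryaa, -3.87 to -2.37 for Dlk1, -3.39 to -1.79 for Cyb5r2, -3.19 to -1.64 for Dusp13b, -3.18 to -1.67 for Adrm1 and 1.76 to 2.99 for Apoe. Chat's bound holds for all arrays only, with fitted values -1.47 without sham 7 d replicate 3 and -1.09 with the table arrays. Calls ended with 1 array left out for Lgals3 (sham 7 d replicate 6), Atf3 (9 of 12 arrays), Cryaa (10 of 12) and Mme (9 of 12).

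**Figure D3:**
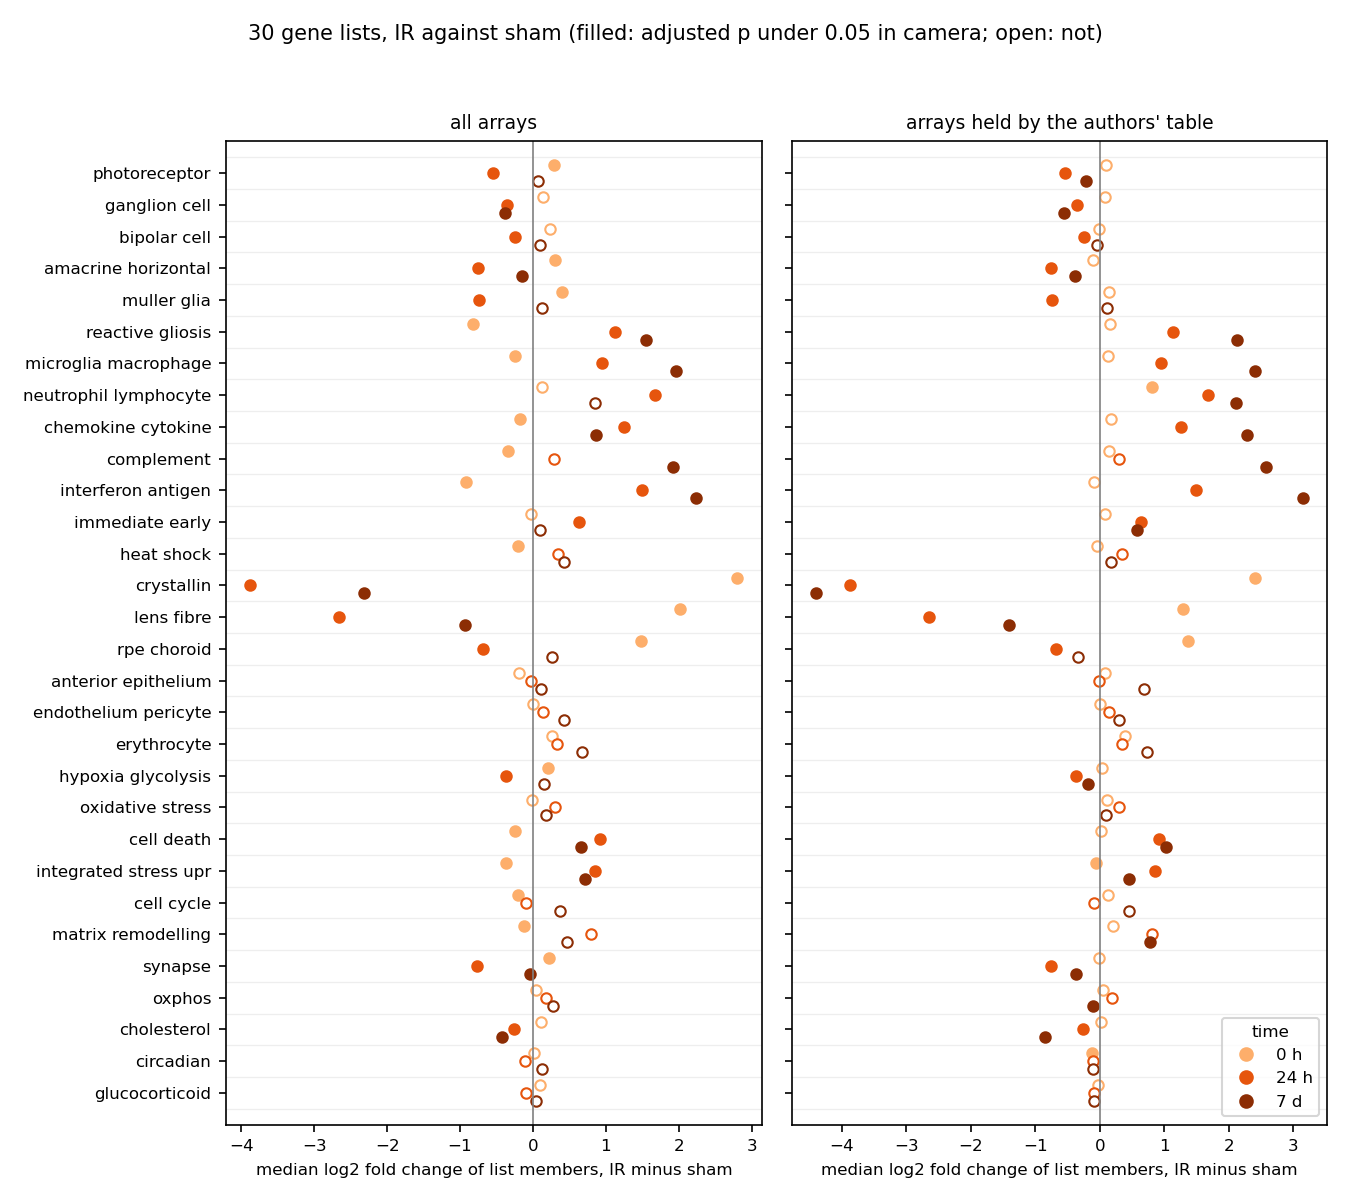
Median log2 fold change of the members of 30 gene lists, IR minus sham, at 0 h, 24 h and 7 d, with all 36 arrays (left) and the table arrays (right); filled points had a camera adjusted p under 0.05. The interferon list lay highest at 7 d and the crystallins lowest at 24 h with all arrays.

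The series title speaks of phases, and the interaction comparisons asked whether the IR effect itself differed between times. From 0 h to 24 h large rises of the effect were in Fosl1 (6.39 ± 1.37, adjusted p = 0.00164; 2 of 6 IR 0 h arrays were well above background), Atf3 (6.36 ± 0.69, adjusted p = 1.10e-07), Nes (5.90), Hmox1 (5.81) and Clcf1 (5.81). It fell most in crystallins, Cryaa (-8.44), Crybb2 (-8.16), Crybb3 (-8.02), Cryba2 (-7.92) and Cryba4 (-7.10). The effect differed in 3888 genes, 1834 toward higher and 2054 toward lower values. Interferon genes shifted up (15 rose, 0 fell and 15 were not called; camera adjusted p = 2.11e-10, and adjusted p = 0.529 with an estimated correlation). Synapse genes shifted down (0 rose, 12 fell and 17 were not called; camera adjusted p = 8.58e-10, and adjusted p = 0.283 with an estimated correlation). Photoreceptor markers did as well (0 rose, 9 fell and 19 were not called; camera adjusted p = 1.18e-06, and adjusted p = 0.686 with an estimated correlation). Sizes that moved by over 1.5 times with the table arrays were Fosl1 4.65, Atf3 5.33, Nes 4.27, Hmox1 4.09, Clcf1 4.23, Cryaa -7.42, Crybb2 -7.17, Crybb3 -7.12, Cryba2 -6.90 and Cryba4 -6.27. Leaving out IR 0 h replicate 3 and sham 0 h replicates 1, 2 and 6, each alone, moved sizes by over 1.5 times, with ranges of 5.68 to 6.81 for Fosl1, 5.24 to 6.26 for Nes, 5.10 to 6.17 for Hmox1, 5.17 to 6.14 for Clcf1, -9.08 to -7.90 for Cryaa, -8.81 to -7.65 for Crybb2, -8.67 to -7.59 for Crybb3 and -8.55 to -7.39 for Cryba2.

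From 24 h to 7 d large rises of the effect were in Serpina3n (5.40 ± 1.19, adjusted p = 0.00297), the thyroid hormone deiodinase Dio1 (4.92) and the complement genes Cfb (4.59) and C1s (4.41). It fell in Reg3b, the chemokine Ccl24, Capn8, the cytokine Il11 and Serpinb2 (adjusted p from 2.85e-04 to 0.0152). Of the 4 groups, only IR at 24 h had arrays well above background for these, so no size is given. It differed in 2609 genes, 1834 toward higher and 775 toward lower values. Complement genes shifted up (9 rose, 0 fell and 10 were not called; camera adjusted p = 1.58e-05, and adjusted p = 0.515 with an estimated correlation). Immediate early genes shifted down (1 rose, 8 fell and 28 were not called; camera adjusted p = 0.00216, and adjusted p = 0.686 with an estimated correlation). Synapse genes shifted up (8 rose, 0 fell and 21 were not called; camera adjusted p = 2.50e-04, and adjusted p = 0.686 with an estimated correlation). Of genes changed at 24 h and 7 d, 1060 were higher at both (479 for independent calls), 289 lower (106) and 205 opposite. As both times share a fit and slide 8, calls are not independent. Serpina3n moved by over 1.5 times (4.67) with the table arrays, which ended the Il11 call. Leaving out sham 7 d replicates 4 and 6, each alone, moved sizes by over 1.5 times, with ranges of 4.80 to 6.05 for Serpina3n and 4.06 to 5.05 for C1s.

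From 0 h to 7 d the effect rose most in Edn2 (5.83), Gbp2 (5.76), Mx2 (5.67) and Serpina3n (5.07). It rose in Ifit3 as well (adjusted p = 0.0122), with no size since no sham 7 d array was well above background for it. The largest falls were in Crybb3 (-7.67), Cryaa (-7.23), Cryba1 (-6.67), Crybb2 (-6.55) and Cryba2 (-6.41). The effect differed in 1225 genes (829 up, 396 down). Interferon genes shifted up (24 rose, 0 fell and 6 were not called; camera adjusted p = 2.81e-26, and adjusted p = 0.279 with an estimated correlation). So did microglia and macrophage markers (15 rose, 0 fell and 14 were not called; camera adjusted p = 9.95e-17, and adjusted p = 0.279 with an estimated correlation). With the table arrays the interaction counts were 10339, 8542 and 4097 genes in the order given. Without sham 7 d replicate 3 the second and the third count were 6997 and 4912, and without sham 0 h replicate 2 the third was 609. Sizes that moved by over 1.5 times with the table arrays were Edn2 4.79, Gbp2 4.03, Serpina3n 2.79, Cryaa -8.68, Cryba1 -7.48, Crybb2 -8.45 and Cryba2 -7.69. Leaving out IR 0 h replicate 3, IR 7 d replicate 5, sham 0 h replicates 1, 2 and 6 and sham 7 d replicates 2, 3, 4, 5 and 6, each alone, moved sizes by over 1.5 times, with ranges of 4.89 to 6.83 for Edn2, 5.06 to 6.47 for Gbp2, 5.19 to 6.47 for Mx2, 4.41 to 5.72 for Serpina3n, -8.48 to -7.05 for Crybb3, -8.40 to -6.31 for Cryaa, -7.78 to -6.02 for Cryba1, -7.55 to -5.71 for Crybb2 and -7.31 to -5.66 for Cryba2. The Crybb2 call ended without sham 0 h replicate 1.

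The sham comparisons asked how retina changed over time after surgery without ischemia. At 24 h against 0 h, Serpina3n (5.18 ± 0.84, adjusted p = 4.97e-04) and Dlk1 (4.21) were the largest rises, and Cpox (4.10; 6 and 2), Exosc7 (at least 6.65-fold higher; 6 and 0) and Nudt9 (3.93; 6 and 4) rose. Where some of the 6 arrays of a group were not well above background, the numbers that were follow the value, the later group first. Falls were in Lrrc43 (at least 3.01-fold lower; 0 and 5), Ccl3 (-3.52; 5 and 6), Muc5ac (-2.95; 3 and 5), Gp2 (-2.95; 3 and 4) and Acox2 (at least 2.72-fold lower; 0 and 5). In all 1674 genes changed (900 higher, 774 lower). Reactive gliosis genes were higher as a group (5 rose, 0 fell and 21 were not called; camera adjusted p = 4.12e-05, and adjusted p = 0.696 with an estimated correlation). The crystallins were too (0 rose, 0 fell and 13 were not called; camera adjusted p = 2.63e-09, and adjusted p = 0.405 with an estimated correlation). Cpox and Exosc7 also differed between slides within the IR groups. Within IR 24 h Exosc7 was 3.87 higher on slide 3 than on slide 2 (well above background on 1 of the 2 IR 24 h arrays of slide 2), and Cpox 2.86 higher, against 0.18 for Gfap and 0.13 for Serpina3n. The signs of Cpox and Exosc7 turned with another background correction, and that of Nudt9 with the set of slides as a block. With the table arrays 8034 genes changed (2423 higher, 5611 lower). With arrays closer than the sampling noise averaged, 30 genes changed. The table arrays moved sizes by over 1.5 times, to Serpina3n 6.73, Nudt9 2.96 and Gp2 -4.04. Leaving out sham 0 h replicates 1 and 2 and sham 24 h replicate 2, each alone, moved sizes by over 1.5 times, with ranges of 4.72 to 5.83 for Serpina3n and 3.89 to 4.82 for Dlk1. With 1 array left out, calls ended for Muc5ac (12 of 12 arrays) and Acox2 (without sham 0 h replicate 2).

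**Figure D4:**
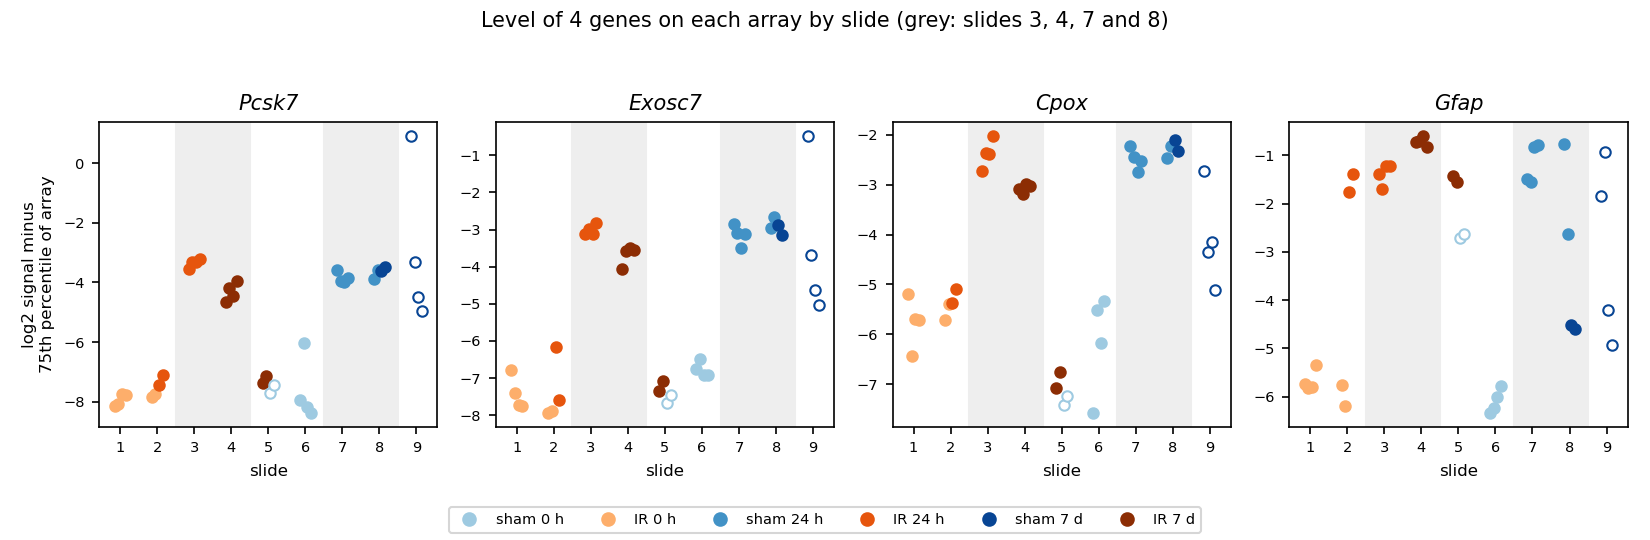
Log2 signal minus the 75th percentile of the array for 4 genes on each array, by slide, coloured by group; open points are the 6 arrays that the authors' table does not hold. Pcsk7, Exosc7 and Cpox were higher on slides 3, 4, 7 and 8 than on slides 1, 2, 5 and 6 by mean.

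At 7 d against 24 h in sham, Cyp2c7, Lrrc43, Doxl2 and Mep1a were called higher (adjusted p from 0.00185 to 0.00490). At most 1 of the 12 arrays was well above background for any, so no size is given. The largest falls were in Serpina3n (-3.66; 4 and 6), Cryba4 (-3.52; 4 and 6), Crygc (-3.38; 4 and 6), Rps7 (-2.56; 3 and 6) and Crygd (-2.51), where Cryba4, Crygc and Crygd are crystallins and Rps7 is a ribosomal protein gene. In all 7570 genes changed (5570 higher, 2000 lower). With the table arrays 213 changed (60 higher, 153 lower), and of the calls over all arrays 60 were made again in the same direction and 1430 had the opposite sign. Without slide 9 the count was 9. It was 0 (limma) with arrays closer than the sampling noise averaged, with the slide as a fixed block and with the arrays of slide 8 alone, where 6410, 129 and 1603 genes had an unadjusted p under 0.05. Serpina3n kept its fall with the table arrays (-2.94, adjusted p = 0.0289), and Rps7 had 0.0015. With the table arrays Cryba4 (-0.96), Crygc (-1.72) and Crygd (-1.66) moved by over 1.5 times. Their calls and those of the named rises ended. Leaving out sham 24 h replicates 1 and 2 and sham 7 d replicates 2, 3, 4, 5 and 6, each alone, moved sizes by over 1.5 times, with ranges of -4.31 to -3.07 for Serpina3n, -4.33 to -2.60 for Cryba4, -4.04 to -2.87 for Crygc and -3.12 to -2.03 for Crygd. Calls that ended with 1 array left out were those of Cryba4 (without sham 7 d replicate 4), Rps7 (without sham 7 d replicate 4) and Crygd (5 of 12 arrays).

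At 7 d against 0 h in sham, rises were in Pcsk7 (at least 5.70-fold higher; 2 and 0), Spint2 (at least 6.15-fold higher; 2 and 0), Exosc7 (at least 5.18-fold higher; 2 and 0) and Dlk1 (3.63; 2 and 6), and falls in Gp2 (at least 2.08-fold lower; 0 and 4), Emp1 (-1.80; 4 and 6), Lamc1 (-1.66; 3 and 6), Rpl5 (-1.59) and Orc1 (-1.59; 2 and 6). Here 2505 genes changed (1411 higher, 1094 lower), and 653 with the table arrays (243 higher, 410 lower). Of the calls over all arrays, 182 were made again in the same direction there and 370 had the opposite sign. The count was 804 without slide 9 and 909 with arrays closer than the sampling noise averaged. Pcsk7 and Exosc7 also differed between slides within the IR groups. The signs of Rpl5 and Orc1 turned with the table arrays and the set of slides as a block. The table arrays moved sizes by over 1.5 times, to Dlk1 5.30, Emp1 -0.89 (call ended), Lamc1 -0.074 (call ended), Rpl5 -0.21 (call ended) and Orc1 -0.16 (call ended). The calls of Spint2 and Exosc7 ended with them. Leaving out sham 7 d replicate 3 or 5 moved Dlk1 by over 1.5 times, with a range of 2.84 to 4.34. The bounds of Pcsk7 and Spint2 rest on values that moved by over 1.5 times without sham 7 d replicate 3.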

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

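The tests of sham 0 h replicates 1 and 2, of slide 9, of sham 7 d replicate 4, of lens tissue, of the sets of slides and the splits of averaged samples were chosen only after the result was seen, the second test of slide 5 was added after the outcome of the first, and the other splits of the arrays and the tests of differences between times were planned.

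The first pattern is the 6 sham arrays that the authors' table does not hold. On slide 9 the highest share of spots well above background was 46.9%, against a lowest share of 66.0% elsewhere, so weak hybridisation is a candidate explanation for the low signal of sham 7 d replicates 3 to 6, while sham 0 h replicates 1 and 2 had at least 70.9%, which argues against it there. These 2 arrays correlated across genes with IR 7 d (0.62 and 0.69) and not with sham 0 h replicates 3 to 6 (-0.21 and -0.28), a smaller difference of 0.825 against at most 0.336 for a table array, which fits a mislabelled or mixed sample. They lay on slide 5 with IR 7 d replicates 5 and 6, correlated with those at 0.775 and 0.809 and with IR 7 d on slide 4 at 0.42 and 0.50, and the first test of a slide 5 batch (best other group minus these, -0.157) fits such a batch, whereas the second gave a correlation across genes of 0.750 between their difference from replicates 3 to 6 and the IR effect at 24 h measured on other slides, which argues against a batch with no injury profile. With IR 24 h they correlated less (0.35 and 0.38), but some genes, chosen after the values were seen, lay near it. Log2 signals of the 2 arrays were Atf3 4.483 and 4.069 (IR 24 h 4.671, IR 7 d 2.231), Cd14 0.465 and 0.335 (IR 24 h 0.750, IR 7 d -2.161), Emp1 -0.740 and -0.698 (IR 24 h -0.608, IR 7 d -3.277), Rcvrn 5.032 and 5.353 (IR 24 h 5.165, IR 7 d 6.556), C3 1.695 and 1.296 (IR 24 h 1.332, IR 7 d 4.307). The 2 arrays thus match neither group throughout. A mislabelled or mixed sample, with or without a batch of slide 5, stays open, and so does an injury of these sham eyes, which was not tested apart from it; genes are not independent replicates in these correlations.

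For sham 7 d replicate 4, tests added after its values were seen argue against weak signal alone but cannot exclude it. It correlated across genes with IR 7 d at 0.63 and with sham 7 d replicates 1 and 2 at -0.46, a difference of 1.09 against at most 0.740 for a table array or another array of slide 9. Replicates 5 and 6 were about as weak (43.3% and 46.9% of spots well above background, against 41.1%), yet its correlation with IR 7 d was 0.389 above theirs. Its mean log2 signals, centred per gene, were 1.80 for microglia and macrophage markers (replicates 5 and 6 -0.37 and -0.87), 1.81 for interferon and antigen presentation genes (replicates 5 and 6 -0.78 and -0.97) and 1.39 for complement genes (replicates 5 and 6 -0.36 and -0.82). A mislabelled or mixed sample fits, and an injury of that eye was not tested apart from it. The 7 d contrasts with sham include this array.

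The second pattern is the fall of crystallins at 24 h. Over 24 samples within groups, the mean of lens fibre genes other than crystallins went with the mean of crystallins (Pearson r = 0.937, permutation p = 1e-05, the smallest that the permutations can give; Spearman correlation = 0.831, permutation p = 2e-05; r = 0.902 without the 2 farthest samples). The lens fibre genes had a median log2 fold change of -2.65 at 24 h, beside -3.88 for the crystallins, which argues against a change of crystallin genes alone. Crystallin means (centred per gene) in sham 24 h were -0.24 and -0.22 on replicates 1 and 2. They were 3.24 to 3.59 on replicates 3 to 6, and -2.13 to -0.80 in IR 24 h. Much of the fall thus rests on sham replicates 3 to 6. A differing share of lens tissue in the samples may explain the pattern, and whether the surgery or the dissection brought it was not tested.

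The third pattern is a set of genes higher in sham at 24 h than at 0 h and higher on slides 3 and 4 than on slides 2 and 5 within the IR groups. Among 223 genes over 4-fold higher on slide 3 than on slide 2 within IR 24 h, 189 (84.8%) were over 2-fold higher on slide 4 than on slide 5 within IR 7 d, with a median of 3.08, so a batch of slides is a candidate explanation. The 2 slide differences correlated across genes at 0.672, against -0.106 and 0.104 for other pairs of slides. The 335 genes over 4-fold higher in sham at 24 h had a median slide difference of 1.84 within IR 24 h, which time after surgery alone does not give. Of 156 genes over 4-fold higher in both slide differences, 147 were called in sham at 24 h against 0 h, 64 at 7 d against 0 h and 20 at 7 d against 24 h, and 16, 10 and 0 (limma) in IR against sham at 24 h, 7 d and 0 h.

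For each count, 100 splits of the compared arrays into groups of the same sizes were counted, the real one included. A count is called rare where under 5% of them gave as many genes. The splits moved arrays across slides, and no slide held IR and sham of the same time. A rare count therefore does not tell treatment or time from slide. The median of the other splits was 0 or 1 in each test, so even a count of 4 could be rare. Arrays closer than sampling noise may not be separate samples, so splits were also counted with these averaged. The numbers are splits with as many genes, then the real count against the highest of the others. Counts were rare in both ways for IR against sham at 0 h (3 of 100 splits, 35 against 3158; averaged, 3 of 100 splits, 4 against 1632) and IR against sham at 24 h (1 of 100 splits, 7294 against 201; averaged, 1 of 56 splits, 2753 against 5). The same held for IR against sham at 7 d (3 of 100 splits, 3984 against 5911; averaged, 1 of 100 splits, 2979 against 1901) and the IR effect at 24 h minus that at 0 h (1 of 100 splits, 3888 against 1940; averaged, 2 of 100 splits, 1594 against 1783) and for the IR effect at 7 d minus that at 0 h (2 of 100 splits, 1225 against 5845; averaged, 2 of 100 splits, 444 against 2979). Counts were rare for arrays but not for averaged samples for the IR effect at 7 d minus that at 24 h (1 of 100 splits, 2609 against 235; averaged, 7 of 100 splits, 949 against 7291) and sham at 24 h against 0 h (1 of 100 splits, 1674 against 246; averaged, 5 of 56 splits, 30 against 379). For sham at 7 d against 24 h the count was rare for arrays (1 of 100 splits, 7570 against 5019). The averaged test is void there, since the real count was 0 (limma, 6410 genes at an unadjusted p under 0.05), so that each of 84 splits had as many (highest 12664). The count was rare in neither way for sham at 7 d against 0 h (13 of 100 splits, 2505 against 8087; averaged, 12 of 100 splits, 909 against 6144). Other splits called several times the real count in several of these, which points to a structure of the samples, such as sham 0 h replicates 1 and 2 or slide 9.

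The IR effect differed between times by a test of the difference itself (limma). From 0 h to 24 h, 3888 genes differed. Named genes with a larger later effect were Fosl1 6.39, Atf3 6.36, Nes 5.90, Hmox1 5.81, Clcf1 5.81, Il1b 3.32 and Ccl2 3.15. Those with a smaller one were Vegfa -0.99, C3 -1.29, Pou4f1 -2.51, Cryba4 -7.10, Cryba2 -7.92, Crybb3 -8.02, Crybb2 -8.16 and Cryaa -8.44, and adjusted p ran from 1.10e-07 to 0.0256. From 24 h to 7 d, 2609 genes differed. Named genes with a larger later effect were Serpina3n 5.40, Dio1 4.92, Cfb 4.59, C1s 4.41, C3 4.22, Gfap 2.64, Aif1 2.07 and Pou4f1 1.64. Those with a smaller one were Atf3 -3.02, and adjusted p ran from 1.76e-08 to 0.0402. From 0 h to 7 d, 1225 genes differed. Named genes with a larger later effect were Edn2 5.83, Gbp2 5.76, Mx2 5.67, Serpina3n 5.07, Gfap 3.36, Atf3 3.34, C3 2.93 and Aif1 2.52. Those with a smaller one were Cryba2 -6.41, Crybb2 -6.55, Cryba1 -6.67, Cryaa -7.23 and Crybb3 -7.67, and adjusted p ran from 9.17e-05 to 0.0209.

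In groups of 5 or 6 samples, the highest or lowest sample stood far from the others in 76 of 695 sets of values (139 genes in 5 groups), where chance gives about 1 in 20, and sham 24 h, with 3 samples, was not tested. In IR 7 d the far sample was the lowest for 19 genes and the highest for 7, while in sham 7 d it was the lowest for 12 and the highest for 13. The values are the gap to the nearest sample divided by the range. In IR 7 d these were Rpe65 0.786, Pon1 0.684, Gp2 0.653, Hmox1 0.708, C3 0.843, Aif1 0.633, Vegfa 0.667, Nes 0.630 and Gja3 0.649. IR 7 d also had Cryba1 0.703, Arr3 0.716, Gap43 0.759, Edn2 0.673, Gpnmb 0.784, Srebf2 0.719, Mx2 0.812, Irf7 0.708 and Oas1a 0.862. IR 7 d also had Rsad2 0.781, Oasl2 0.754, Cd68 0.856, C1qc 0.733, Icam1 0.641, Birc3 0.836, Ifit3 0.680 and Lamc1 0.690. In IR 0 h these were Kcnj13 0.781, Atf3 0.815, Glul 0.726, Cd8a 0.835, Ecel1 0.843, Clcf1 0.726, Bcl2a1 0.734 and Omd 0.770. IR 0 h also had Gpnmb 0.799, Mmp12 0.764, Serpina3n 0.759, Adrm1 0.714, Icam1 0.726, Serpinb2 0.731, Lrrc43 0.754 and Muc5ac 0.840. In IR 24 h these were Kcnj13 0.764, Crybb1 0.846, Il1b 0.761, Asns 0.758 and C1qc 0.796. In sham 7 d these were Hmox1 0.715, C3 0.701, Pou4f1 0.869, Thy1 0.821, Egfl6 0.747, Arr3 0.665, Gap43 0.729, Trpm1 0.891 and Gbp2 0.638. Sham 7 d also had Fcgr3a 0.711, Bfsp2 0.637, Rrh 0.726, Hk2 0.708, Chac1 0.633, Asns 0.676, Gria4 0.637, Irf7 0.629 and Oasl2 0.737. Sham 7 d also had Cyb5r2 0.669, Dusp13b 0.674, Adrm1 0.696, Chat 0.632, Cd68 0.727, Pcsk7 0.722 and Spint2 0.723. In sham 0 h these were Gja3 0.771, Acox2 0.806, Crygc 0.749 and Crygd 0.788.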

How the results depend on the processing

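The alternatives that use the table arrays, averaged arrays, the authors' table with all columns as deposited, arrays without slide 9 or 5, the set of slides as a block, and slide 8 or the slide as a fixed block were chosen only after the result was seen, and the others were planned. Counts are in the order of the contrasts: IR against sham at 0 h, 24 h and 7 d, the IR effect at 24 h minus 0 h, 7 d minus 24 h and 7 d minus 0 h, and sham at 24 h against 0 h, 7 d against 24 h and 7 d against 0 h. Where no cause is given, the cause was not tested.

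The counts over all arrays were 35, 7294, 3984, 3888, 2609, 1225, 1674, 7570 and 2505 genes. Normexp background correction gave 3, 2911, 472, 1545, 778, 97, 11535, 15137 and 0. Quantile normalisation gave 1, 4690, 5137, 2599, 2338, 1932, 504, 3872 and 2439. Only the compared arrays gave 249, 16731, 542, 12720, 1603, 161, 8079, 3 and 135. The slide as a random block gave 6, 4564, 1307, 2644, 1192, 219, 457, 1745 and 477. The slide correlation was 0.133. The 0 with normexp is from limma, with 1697 genes at an unadjusted p under 0.05. Array weights gave 8881, 20135, 17235, 15184, 14500, 11186, 21352, 14793 and 8360. The authors' table with copied columns used once gave 1322, 12768, 6946, 9078, 7816, 2879, 7214, 235 and 611 of 20142 genes tested. An adjusted p under 0.01, a stricter threshold, gave 8, 3960, 1530, 1791, 1107, 262, 411, 2939 and 656.

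Median centring moved IR against sham at 0 h to 6. No filter moved IR against sham at 7 d to 7077, sham at 7 d against 24 h to 16418 and sham at 7 d against 0 h to 10411, of 35498 genes tested. A 2-fold minimum moved IR against sham at 7 d to 2583 and sham at 7 d against 0 h to 1602. The other counts under these 3 settings stayed within 1.5 times. So did all 9 under the replicate block, the filter on 6 of 6 arrays and the mean of a gene's probes.

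The table arrays gave 1536, 17132, 11368, 10339, 8542, 4097, 8034, 213 and 653. Averaged arrays (fewer samples) gave 4, 2753, 2979, 1594, 949, 444, 30, 0 and 909. Averaged table arrays gave 1086, 14867, 11175, 7942, 6995, 2490, 1679, 31 and 273. The authors' table with all columns as deposited (copies counted as samples) gave 3931, 13486, 11753, 10686, 10977, 6910, 9971, 3574 and 5923. Slide 9 left out gave 989, 16171, 8967, 13387, 6309, 7304, 11183, 9 and 804. The table arrays without slide 5 gave 2271, 18091, 11218, 11425, 9023, 3991, 9895, 283 and 2327. The table arrays and the slide as a random block gave 300, 15525, 10006, 8006, 7141, 2378, 4205, 160 and 288. The table arrays and the set of slides as a block gave 2382, 17398, 11624, 11250, 10172, 4237, 2896, 269 and 279. For sham at 7 d against 24 h, the slide as a fixed block gave 0 genes (limma, 129 at an unadjusted p under 0.05). The arrays of slide 8 alone gave 0 (limma, 1603 unadjusted), and averaged arrays gave 0 (limma, 6410 unadjusted).

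Leaving out 1 array at a time gave ranges of 13 to 39, 5986 to 6684, 3043 to 8520, 2671 to 4297, 2128 to 6997, 609 to 4912, 649 to 2016, 5391 to 10384 and 1688 to 5525 genes. Single arrays moved some counts over 1.5 times. For IR against sham at 0 h the count was 13 without IR 0 h replicate 5. It was 18 without IR 0 h replicate 1, sham 0 h replicate 1 or sham 0 h replicate 2. At 7 d the count was 8520 without sham 7 d replicate 3. For the IR effect at 7 d minus that at 24 h the counts were 3932 and 6997 without sham 7 d replicates 2 and 3. For 7 d minus 0 h the counts were 766 and 773 without IR 0 h replicates 1 and 5. They were 619 and 609 without sham 0 h replicates 1 and 2, and 4912 and 2728 without sham 7 d replicates 3 and 4. For sham at 24 h against 0 h the counts were 649 and 722 without sham 0 h replicates 1 and 2. They were 844, 802 and 797 without sham 24 h replicates 3, 4 and 5. For sham at 7 d against 0 h the counts were 5490 and 5525 without sham 7 d replicates 1 and 2. List calls, 50 of 90 with camera, ranged from 43 to 55. They were 1 with an estimated correlation and 27 with fry.

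The sign of some named genes turned where the gene was called with the main setting or with the alternative; turns of values called in neither are not listed. The fitted log2 fold changes, also where a group lay at background, were as follows. With normexp background correction they were Cpox -0.27 (sham 24 h against 0 h), Exosc7 -0.45 (sham 24 h against 0 h), Lif -0.037 (7 d), Mitf -0.027 (7 d), Nr0b2 -0.13 (0 h), Slc2a3 -0.036 (7 d), Slc7a11 0.077 (24 h), Tpx2 -0.13 (7 d) and Vamp2 0.15 (7 d). With array weights they were Glul -0.84 (0 h), Uqcrc2 -0.15 (7 d) and Vegfa -0.44 (7 d). With the table arrays and the set of slides as a block they were Nudt9 -0.96 (sham 24 h against 0 h), Orc1 0.094 (sham 7 d against 0 h), Pdgfrb -0.0013 (7 d), Rp1 -0.052 (7 d), Rpl5 0.12 (sham 7 d against 0 h), Rps7 0.0015 (sham 7 d against 24 h) and Vegfa -0.54 (7 d). With the authors' table with copied columns used once they were Rp1 -0.049 (7 d), Rps7 0.00051 (sham 7 d against 24 h) and Vegfa -0.52 (7 d). With the table arrays they were Rp1 -0.049 (7 d), Rps7 0.0015 (sham 7 d against 24 h) and Vegfa -0.52 (7 d). With averaged table arrays they were Rp1 -0.049 (7 d) and Vegfa -0.52 (7 d).

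Camera's direction turned for these lists, called with the main setting or with the alternative (turns of lists called in neither are not listed), given with the median log2 fold change of their members, whose sign may differ from camera's, at 0 h unless stated. For the authors' table with copied columns used once these were amacrine and horizontal cell markers -0.088, cell cycle genes 0.035, chemokines and cytokines 0.041, complement genes -0.0069, matrix remodelling genes 0.15, microglia and macrophage markers 0.10, reactive gliosis genes 0.11 and synapse genes -0.011. For the table arrays these were amacrine and horizontal cell markers -0.11, cell cycle genes 0.12, chemokines and cytokines 0.17, complement genes 0.14, hypoxia and glycolysis genes 0.040, matrix remodelling genes 0.21, microglia and macrophage markers 0.12, photoreceptor markers 0.099, reactive gliosis genes 0.16, synapse genes -0.0078 and oxidative phosphorylation genes -0.11 (7 d). For averaged table arrays these were amacrine and horizontal cell markers -0.14, cell cycle genes 0.12, chemokines and cytokines 0.18, complement genes 0.045, hypoxia and glycolysis genes 0.067, matrix remodelling genes 0.18, photoreceptor markers 0.10, reactive gliosis genes 0.16, synapse genes -0.033 and oxidative phosphorylation genes -0.11 (7 d). For normexp background correction these were heat shock genes -0.072. Leaving out sham 7 d replicate 3 turned oxidative phosphorylation genes at 7 d to -0.21, and with 1 array left out at a time their median ran from there to 0.46. Over all arrays, median, mean and camera direction had the same sign for every called list of IR against sham. They differed for some lists not called. At 0 h these were anterior epithelium markers, endothelium and pericyte markers and circadian genes. At 24 h these were complement genes, anterior epithelium markers, endothelium and pericyte markers, cell cycle genes and glucocorticoid targets. At 7 d these were photoreceptor markers, bipolar cell markers, anterior epithelium markers, hypoxia and glycolysis genes, oxidative stress genes, circadian genes and glucocorticoid targets.

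Among the values of named genes, 190 kept direction and call with normexp, 290 with quantile normalisation, 294 with median centring, 247 with the slide as a random block, 287 with the table arrays and 243 with averaged arrays, and the replicate block kept 331. Calls that ended numbered 138, 51, 47, 95, 28 and 99 in that order. The median log2 fold change of all genes, for IR against sham at 0 h, 24 h and 7 d and the 3 sham contrasts, moved with the scaling, and fold changes are to be read relative to it. It was 0.049, 0.14, 0.18, -0.20, 0.091 and -0.051 with the 75th percentile. Median centring gave -0.012, 0.20, -0.042, -0.15, -0.064 and -0.15. Quantile normalisation gave 0.00014, 0.049, 0.28, -0.084, -0.25 and -0.30. Normexp gave -0.17, 0.23, -0.067, -0.63, 0.69 and 0.027. Signal over background limited the sham 7 d group, since 23.5% to 46.9% of spots were well above background on slide 9 and dim genes there lay near background.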
